A study of Homo sapiens with 28 samples.

How the data were processed

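Messenger RNA was sequenced from 28 libraries of human triple negative breast cancer cell lines. Per the labels, polyadenylated RNA was enriched from total RNA, libraries were made with an Illumina TruSeq kit and sequenced on a HiSeq instrument. The authors deposited 2 tables of FPKM (fragments scaled to transcript length and to the number of mapped fragments), 1 for the 20 SUM159 and SUM159R libraries and 1 for the 8 SUM149 and SUM149R libraries, each with 23615 gene rows named by symbol. The processing notes name the genome build hg19, Bowtie2, TopHat2, Cufflinks and Cuffnorm without versions, roles or options. The deposited FPKM values carry the scaling between libraries that Cuffnorm gives, and the method of scaling and the annotation are not stated. Each table was scaled by itself, so values were compared only within a table, and the tables were compared only by their log2 fold changes. Read counts were not used here, so the depth of each library is unknown and no counting intervals can be given. A value of exactly 0 can stand for a gene with no reads or for an estimate that failed, and is described as listed at 0.

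The 28 libraries formed 14 groups of 2 by cell line, treatment and duration. No library column was left unmatched and no library was left out. Genes with an FPKM of at least 1 in at least 2 libraries of a table were kept, which left 13153 genes in the SUM159 table and 13058 in the SUM149 table. Values were transformed as log2(FPKM + 1), and fold changes are therefore on FPKM + 1. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the spread on expression), with 1 fit per table and 1 coefficient per group. All libraries of a table shared the estimate of the spread, with 10 residual degrees of freedom (prior 1.82) in the SUM159 table and 4 (prior 1.97) in the SUM149 table. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and genes with an adjusted p under 0.05 are called. The labels do not say whether the 2 replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical. Replicate numbers were not used as a block. Deviations of equally numbered replicates correlated from -0.32 to 0.214, and negatively in SUM159 at 3, 12 and 24h.

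The comparisons were JQ1 minus DMSO in each line and at each duration, the differences of these responses between the resistant and the parental line and between 24h and 3h in SUM159, and the resistant minus the parental line in DMSO. For SUM159R the last is the mean of the differences at 3h and 24h. The comparisons, the other settings, the gene lists and the rule for naming genes were fixed before the data were examined. For each treatment or line comparison the rule named 12 fixed genes (among them MYC, HEXIM1, SERPINI1, BRD2, BRD3, CCND1, CDKN1A, BCL2L1, FOSL1, EGFR and IL6), the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean FPKM of at least 5 and no overlap between the groups, and up to 4 called members of each list that passed its test. For each difference of responses it named 5 genes each way.

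The 26 gene lists were MYC-linked ribosome biogenesis, BET inhibitor induced genes and polyadenylated histones, BET proteins with P-TEFb and Mediator, CK2 and PP2A subunits, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and p53 targets, BCL2 family and apoptosis, NF-kB and inflammatory cytokines, interferon-stimulated genes, immediate early and AP-1 genes, MAPK feedback, luminal markers, basal markers, mesenchymal and matrix genes, YAP/TEAD targets, WNT targets, receptor tyrosine kinases, ABC drug transporters, cholesterol synthesis, hypoxia and glycolysis, ATF4 and the unfolded protein response, autophagy and lysosome, cytosolic ribosomal proteins, mitochondrially encoded genes, and blood and endothelial cell markers. Lists with at least 5 tested members were tested with camera of limma at its preset correlation of 0.01, adjusted over the 24 lists tested in each comparison. The mitochondrially encoded genes and the blood and endothelial cell markers had fewer than 5 tested members and were not tested. Camera with a correlation estimated from the residuals and fry were run beside it.

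Changes were also compared across genes by Pearson's r and Spearman's rho between comparisons that share no library. Genes are not independent replicates, so these carry no p-value. Other settings fixed at the same time as the comparisons were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, quantile normalization, rescaling by median ratios, a replicate block, a spread taken only from the groups compared, and leaving out each library in turn. Settings chosen after seeing the data were the removal of microRNA, small nucleolar and similar short RNA, the removal of a trend on transcript GC content from each library (loess, span 0.3), the first component of the within-group residuals as a covariate, and a block with the replicate numbers of the JQ1 groups crossed. GC content could be matched for 92.3% of the tested genes of the SUM159 table.

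The fits were tested on 200 genes changed by a known factor in simulated data. In the SUM159 comparison at 3h, 89.6% of genes changed 2-fold and 56.7% of those changed 1.5-fold were called, with 13 false calls. For the difference of responses at 24h the shares were 50.7% and 34.3%. The real spread differed between groups and followed GC content, so these shares and false calls may not hold for the real data. Scripts ran under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.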

Results

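Gene expression was measured by messenger RNA sequencing in SUM159 and SUM149, human triple negative breast cancer lines, and in their JQ1-resistant derivatives SUM159R and SUM149R. JQ1 is a small molecule that displaces the BET bromodomain proteins from acetylated chromatin. Cells received 500 nM JQ1 or its solvent DMSO. SUM159 was sampled at 3, 12 and 24h, SUM159R at 3 and 24h, and SUM149 and SUM149R at 12h, with n = 2 libraries in each of 14 groups. The labels do not say whether the resistant cells were kept in JQ1 before the experiment. Genes are named by the symbols of the deposited tables (hg19), which hold no coordinates.

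The summed FPKM of a library ranged from 868212 to 1587991, and the precursor microRNA MIR4461 alone held from 23.8% to 45.8% of it. From 11225 to 12380 genes reached 1 FPKM in a library. Replicates of a group correlated with r from 0.973 to 0.998 over genes with a mean FPKM of at least 5 once short RNA was left out, and from 0.886 to 0.948 with it. In the SUM159 table the difference between replicates of a group went with transcript GC content across genes, with a Spearman rho from -0.804 to 0.821 depending on the group. Values below are group means ± SD of FPKM (n = 2), and log2 fold changes ± SE of FPKM + 1.

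In SUM159, the earliest effect of JQ1 was asked at 3h, and genes known to mark BET inhibition were among the largest changes. HEXIM1, an inhibitor of the elongation factor P-TEFb, rose from 13.2 ± 2.36 to 62.9 ± 7.79 FPKM (2.17 ± 0.19, adjusted p = 7.2e-06). CDKN1A, which encodes the CDK inhibitor p21, rose from 40.8 ± 4.03 to 175 ± 18.6 FPKM (2.08 ± 0.09, adjusted p = 5.3e-08), and BRD2 rose from 73.8 ± 1.83 to 203 ± 17.9 FPKM (1.44 ± 0.09, adjusted p = 6e-07). The hyaluronan synthase HAS2 fell from 11 ± 1.58 to 0.946 ± 0.0582 FPKM (-2.62 ± 0.15, adjusted p = 3.5e-07), and the deiodinase DIO2 fell by 2.47 on the log2 scale. BCL2L1, which encodes the survival protein BCL-XL, fell from 44.9 ± 4.57 to 24.0 ± 1.57 FPKM (-0.87 ± 0.08, adjusted p = 1.1e-05). The transcription factor gene MYC stood at 173 ± 42.2 FPKM in DMSO and 187 ± 37.5 in JQ1 (0.12 ± 0.21, adjusted p = 0.76), and BRD3 (0.15, adjusted p = 0.52) and FOSL1 (0.30, adjusted p = 0.22) did not pass either.

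Of the 14 tested BET inhibitor induced genes and polyadenylated histones, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 4.56e-10 and adjusted p = 0.0181 with an estimated correlation. They included SERPINI1 (1.66), a protease inhibitor gene, and the histone genes HIST1H2AC (2.05) and HIST1H2BD (1.81). Genes of CDK inhibitors and p53 targets rose as 12 of 21 members against 2 that fell (13 and 2 adjusted over the list alone, camera adjusted p = 2.98e-06, adjusted p = 0.0057 with an estimated correlation). Called members included PLK3 (1.96) and the stress sensor gene SESN2 (1.25). For NF-kB and inflammatory cytokines, 11 of 21 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00272, adjusted p = 0.0205 with an estimated correlation). The cytokine genes IL6 (-1.70), IL8 (-1.61), CCL20 (-1.47) and IL1B (-1.40) were among them. In cholesterol synthesis, 6 of 23 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000557, adjusted p = 0.0189 with an estimated correlation). Among those called were the sterol sensor partner INSIG1 (2.02) and IDI1 (1.39). Genes of ATF4 and the unfolded protein response rose in 8 of 19 and fell in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.00073, adjusted p = 0.0181 with an estimated correlation), with HERPUD1 at 1.21 and TRIB3 at -1.18.

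Immediate early genes, which respond to stimuli without new protein synthesis, rose in 8 of 17 (9 adjusted over the list alone, where 1 fell), with camera adjusted p = 2.43e-06 and adjusted p = 0.172 with an estimated correlation. EGR1 (1.87), FOS (1.83) and ATF3 (1.61) were among them. Of 26 MYC-linked ribosome biogenesis genes, 10 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.211 with an estimated correlation). Receptor tyrosine kinases fell in 4 of 15 and rose in 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.235 with an estimated correlation). Lower were IGF1R (-1.19), PDGFRA (-1.02), EGFR (-0.97) and PDGFRB (-0.83). Hypoxia and glycolysis had 7 of 20 higher and 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.235 with an estimated correlation). Autophagy and lysosome had 6 of 23 higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.00795, adjusted p = 0.0601 with an estimated correlation), with the autophagy receptor gene SQSTM1 at 0.91. Cytosolic ribosomal proteins passed with 4 of 28 higher (1 adjusted over the list alone, camera adjusted p = 0.000143, adjusted p = 0.242 with an estimated correlation), and after quantile normalization their median turned from 0.25 to -0.08. In all, 2935 of 13153 genes were called in SUM159 at 3h, 1261 higher and 1674 lower, and 282 changed at least 2-fold. Higher calls were 43% of these and 50.7% after the GC trend was removed. With the spread taken only from the 4 libraries compared, 4 genes were called and the calls of all 57 named genes ended.

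At 12h in SUM159, the same question was asked after longer exposure, and histone genes with polyadenylated transcripts were among the largest rises. HIST2H2BE rose from 0.690 ± 0.0511 to 11.7 ± 0.372 FPKM (2.91 ± 0.10, adjusted p = 2.2e-08), and the reductase gene DHRS2 rose from 0.676 ± 0.16 to 9.65 ± 0.332 FPKM (2.67 ± 0.12, adjusted p = 7.1e-08). The interleukin 7 receptor gene IL7R fell from 24.1 ± 2.71 to 1.40 ± 0.0462 FPKM (-3.38 ± 0.13, adjusted p = 3e-08), and PRRX1, a homeobox gene of mesenchymal cells, fell by 2.23 on the log2 scale. SERPINI1 (2.26), HEXIM1 (1.65), CDKN1A (1.51) and BRD2 (0.97) were higher. MYC (-0.09, adjusted p = 0.81), BCL2L1 (-0.07, adjusted p = 0.61), EGFR (-0.10, adjusted p = 0.63) and FOSL1 (-0.25, adjusted p = 0.3) did not pass.

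DNA replication genes were lower at 12h: of 27 G1/S members 18 fell and 1 rose (19 and 1 adjusted over the list alone, camera adjusted p = 6.25e-08, adjusted p = 0.00154 with an estimated correlation). The replicative helicase genes MCM2 (-1.15) and MCM5 (-1.31) and the cell cycle transcription factor E2F2 (-1.60) were examples. In the BET inhibitor induced list 13 of 14 rose (13 adjusted over the list alone, camera adjusted p = 1.23e-12, adjusted p = 0.00594 with an estimated correlation). NF-kB and inflammatory cytokines fell in 13 of 21 with none higher (13 and 0 adjusted over the list alone, camera adjusted p = 2.81e-05, adjusted p = 0.00571 with an estimated correlation). CDK inhibitors and p53 targets had 10 of 21 higher and 3 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.00532, adjusted p = 0.0291 with an estimated correlation). Genes of autophagy and the lysosome rose in 9 of 23 and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.000974, adjusted p = 0.0279 with an estimated correlation).

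A further group of lists passed camera at 12h at the preset correlation only. MYC-linked ribosome biogenesis genes fell in 12 of 26 and rose in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.0862 with an estimated correlation). G2/M genes fell in 11 of 26 and rose in 0 (12 and 1 adjusted over the list alone, adjusted p = 0.308 with an estimated correlation). Interferon-stimulated genes fell in 11 of 24 and rose in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.0883 with an estimated correlation), with IFI44L at -1.57. MAPK feedback genes fell in 8 of 17 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.058 with an estimated correlation). Basal markers fell in 8 of 17 and rose in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0504 with an estimated correlation). Mesenchymal and matrix genes fell in 8 of 27 (9 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation), with the membrane protease gene MMP14 at -1.12. YAP/TEAD targets fell in 9 of 22 and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.171 with an estimated correlation). Receptor tyrosine kinases fell in 7 of 15 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation), with PDGFRA at -1.31. Hypoxia and glycolysis genes rose in 11 of 20 and fell in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.0883 with an estimated correlation), with NDRG1 at 1.13. Cytosolic ribosomal proteins rose in 1 of 28 (0 adjusted over the list alone, adjusted p = 0.308 with an estimated correlation), and their median turned from 0.18 to -0.07 after quantile normalization. In all, 4043 genes were called at 12h, 1766 higher and 2277 lower, and 313 changed at least 2-fold.

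After 24h in SUM159, serpin genes were among the largest falls. SERPINB3, a squamous epithelial serpin gene, fell from 68.9 ± 1.56 to 0.524 ± 0.106 FPKM (-5.52 ± 0.10, adjusted p = 9.3e-12), and its close paralog SERPINB4, whose reads are hard to tell apart from it, fell by 5.26 on the log2 scale. The stress response gene NUPR1 fell from 45.6 ± 0.0544 to 1.83 ± 0.247 FPKM (-4.05 ± 0.21, adjusted p = 5.9e-08). PEG10, a gene of retrotransposon origin, rose from 53.2 ± 2.37 to 449 ± 48.7 FPKM (3.05 ± 0.10, adjusted p = 2.3e-09). HEXIM1 (1.86), CDKN1A (1.48), SERPINI1 (1.22) and BRD2 (1.08) stayed higher, and MYC (-0.24, adjusted p = 0.4) and EGFR (0.27, adjusted p = 0.11) did not pass.

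Mitotic genes fell at 24h: 24 of 26 G2/M members were lower and 0 higher (25 and 0 adjusted over the list alone, camera adjusted p = 8.89e-12, adjusted p = 0.0451 with an estimated correlation). Among those called were the cyclin gene CCNA2 (-1.35), the kinase gene AURKA (-1.31) and TOP2A (-1.30). Among 27 G1/S members 18 fell and 3 rose (18 and 3 adjusted over the list alone, camera adjusted p = 0.000343, adjusted p = 0.0178 with an estimated correlation), with GINS2 at -1.02 and CCNE1 at 1.01. Interferon-stimulated genes fell in 16 of 24 and rose in 1 (16 and 2 adjusted over the list alone, camera adjusted p = 0.000152, adjusted p = 0.026 with an estimated correlation), with OAS2 at -1.99 and IFI44L at -1.94. ATF4 and unfolded protein response genes fell in 11 of 19 (11 adjusted over the list alone, camera adjusted p = 0.000343, adjusted p = 0.0178 with an estimated correlation). Examples were CHAC1 (-2.54) and the serine synthesis genes PSAT1 (-1.49) and PHGDH (-1.30). Cholesterol synthesis fell in 11 of 23 and rose in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.026 with an estimated correlation), with HMGCS1 at -1.27. ABC drug transporters rose in 5 of 11 and fell in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00355, adjusted p = 0.026 with an estimated correlation). The efflux pump gene ABCG2 rose from 3.26 ± 0.171 to 12.3 ± 1.47 FPKM (1.64 ± 0.10, adjusted p = 2.5e-07).

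The BET inhibitor induced list rose in 13 of 14 at 24h (13 adjusted over the list alone, camera adjusted p = 2.92e-09, adjusted p = 0.0195 with an estimated correlation), with HIST1H2BD at 2.88 and HIST1H1C at 2.09. NF-kB and inflammatory cytokines fell in 11 of 21 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00412, adjusted p = 0.026 with an estimated correlation), with CXCL2 at -1.57 and IL6 at -1.51. Autophagy and lysosome had 11 of 23 higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.00803, adjusted p = 0.0451 with an estimated correlation). Cytosolic ribosomal proteins had 13 of 28 lower (15 adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.51 with an estimated correlation), and MYC-linked ribosome biogenesis 13 of 26 lower (14 adjusted over the list alone, camera adjusted p = 0.00569, adjusted p = 0.133 with an estimated correlation). In all, 5435 genes were called at 24h, 2252 higher and 3183 lower, and 708 changed at least 2-fold. The share of higher calls was 41.4%, 49.1% after quantile normalization and 49.4% after the GC trend was removed. The same genes were higher at 3, 12 and 24h in 465 cases, where 29 were expected by chance, and lower at all 3 in 681, where 70 were. With the spread taken only from the libraries compared, 2442 genes were called at 12h and 2696 at 24h.

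**Figure D1:**
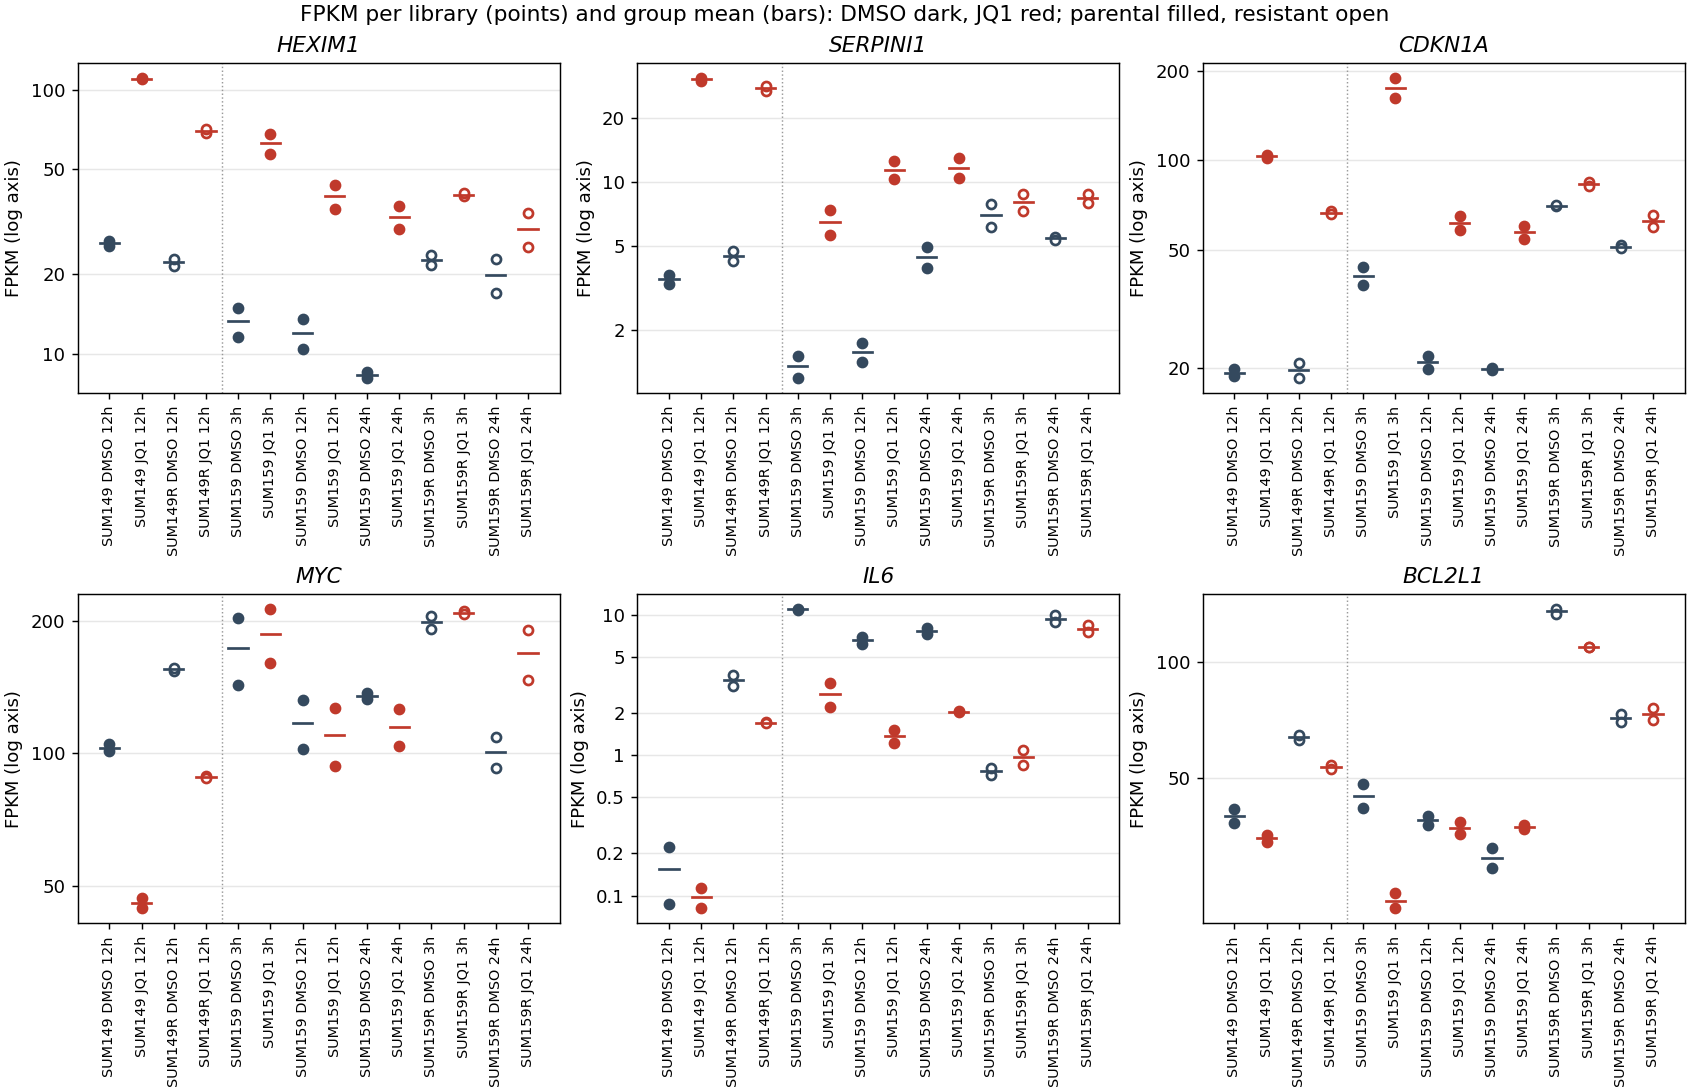
FPKM of HEXIM1, SERPINI1, CDKN1A, MYC, IL6 and BCL2L1 in each of the 28 libraries on a log axis, by line, treatment and duration; dots are libraries, bars are group means (n = 2), JQ1 is red and DMSO dark, parental lines are filled and resistant lines open, and a dotted line separates the 2 tables, which were scaled apart. HEXIM1 in SUM159 stood at 62.9 FPKM with JQ1 and 13.2 with DMSO at 3h, against 40.1 and 22.7 in SUM159R.

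The time course itself was tested as the difference of the JQ1 response in SUM159 at 24h from that at 3h. DKK1, a secreted WNT antagonist, fell at 3h from 162 ± 9.52 to 56.4 ± 9.7 FPKM (-1.51) and rose at 24h from 15.3 ± 0.84 to 51.6 ± 2.01 FPKM (1.69), a difference of 3.20 ± 0.14 (adjusted p = 1.2e-07). The apoptosis gene PMAIP1 rose at 3h (1.17) and fell at 24h (-1.62), a difference of -2.79 ± 0.20 (adjusted p = 2.2e-06). Response differences for SERPINB3 (-5.42) and NUPR1 (-3.69) went with DMSO levels that were higher at 24h, 68.9 against 13.4 FPKM for SERPINB3 and 45.6 against 4.98 for NUPR1. BCL2L1 (1.13), EGFR (1.23) and CCND1 (0.74) moved upward in response from 3h to 24h and CDKN1A (-0.59) and BRD2 (-0.37) downward, while MYC (-0.36, adjusted p = 0.42) and HEXIM1 (-0.31, adjusted p = 0.44) did not pass.

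By list, the response at 24h was below that at 3h for several groups. G2/M genes were lower in 23 of 26 (24 adjusted over the list alone, adjusted p = 0.0395 with an estimated correlation). G1/S genes were lower in 12 of 27 and higher in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.0109 with an estimated correlation). Interferon-stimulated genes were lower in 15 of 24 (16 adjusted over the list alone, adjusted p = 0.0187 with an estimated correlation). Cholesterol synthesis genes were lower in 15 of 23 (15 adjusted over the list alone, adjusted p = 0.00333 with an estimated correlation). Genes of ATF4 and the unfolded protein response were lower in 11 of 19 (12 adjusted over the list alone, adjusted p = 0.00333 with an estimated correlation). Genes of CDK inhibitors and p53 targets were lower in 11 of 21 and higher in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.0395 with an estimated correlation). ABC drug transporters were higher in 6 of 11 (6 adjusted over the list alone, adjusted p = 0.0267 with an estimated correlation). Passing at the preset correlation only, the remaining lists were lower. Immediate early and AP-1 genes were lower in 7 of 17 (9 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Cytosolic ribosomal proteins were lower in 17 of 28 (21 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation). In all, 3681 genes differed, 1506 upward and 2175 downward, 609 by at least 2-fold. Upward calls were 40.9% of these, 49.3% after quantile normalization and 47.7% after the GC trend was removed. With the spread of the 8 libraries compared, 1272 were called.

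In SUM159R, the question was how resistant cells respond to JQ1, and at 3h few genes were called. The bromodomain gene ZMYND8 fell from 10.6 ± 0.487 to 4.89 ± 0.0746 FPKM (-0.97 ± 0.06, adjusted p = 1.7e-05), and RIN2 (-0.94) and KRT80 (-0.85) also fell. EIF2AK3, which encodes the stress kinase PERK, rose from 3.81 ± 0.155 to 8.59 ± 0.731 FPKM (0.99 ± 0.09, adjusted p = 0.00046), and the nuclear RNA NEAT1 rose from 185 ± 20.9 to 366 ± 10.1 FPKM (0.98 ± 0.13, adjusted p = 0.0031). HEXIM1 stood at 22.7 ± 1.33 FPKM in DMSO and 40.1 ± 0.773 in JQ1 (0.80 ± 0.19, adjusted p = 0.063), and BRD2 (0.30, adjusted p = 0.15), CDKN1A (0.24, adjusted p = 0.35), SERPINI1 (0.18, adjusted p = 0.9), IL6 (0.15, adjusted p = 0.87) and MYC (0.07, adjusted p = 1) did not pass.

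ATF4 and unfolded protein response genes rose in 4 of 19 in SUM159R at 3h (5 adjusted over the list alone, camera adjusted p = 2.19e-10, adjusted p = 0.000547 with an estimated correlation). Among those called were HERPUD1 (0.87) and the chaperone gene HSPA5 (0.69). Basal markers fell in 4 of 17 (7 adjusted over the list alone, camera adjusted p = 6.81e-05, adjusted p = 0.00873 with an estimated correlation). Cholesterol synthesis had 1 of 23 higher (1 adjusted over the list alone, camera adjusted p = 0.00207, adjusted p = 0.0328 with an estimated correlation). CDK inhibitors and p53 targets had 0 of 21 called (0 adjusted over the list alone) with a median of 0.13. Their camera adjusted p was 0.00103, and adjusted p = 0.0167 with an estimated correlation. Genes induced by BET inhibitors had 1 of 14 higher (2 adjusted over the list alone, camera adjusted p = 1.16e-05, adjusted p = 0.0512 with an estimated correlation). The other lists passed at the preset correlation only. G1/S genes fell in 0 of 27 (0 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation). MAPK feedback genes fell in 2 of 17 and rose in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation). ABC drug transporters fell in 1 of 11 and rose in 0 (2 and 1 adjusted over the list alone, adjusted p = 0.0512 with an estimated correlation). G2/M genes fell in 0 of 26 (1 adjusted over the list alone, adjusted p = 0.517 with an estimated correlation). Receptor tyrosine kinases fell in 2 of 15 (2 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation). Hypoxia and glycolysis genes rose in 0 of 20 (0 adjusted over the list alone, adjusted p = 0.2 with an estimated correlation). Autophagy and lysosome genes rose in 0 of 23 (1 adjusted over the list alone, adjusted p = 0.095 with an estimated correlation). Cytosolic ribosomal proteins rose in 0 of 28 (0 adjusted over the list alone, adjusted p = 0.517 with an estimated correlation), and their median turned from 0.07 to -0.03 after quantile normalization. In all, 190 genes were called, 54 higher and 136 lower, and 7 changed at least 2-fold. The count was 72 after quantile normalization and 8 with the spread of the 4 libraries compared. It was 888 after the GC trend was removed, where 39.4% of calls were higher against 28.4% before. Replicates differed with an SD of 0.149 and 0.126 in DMSO and JQ1 here, and 0.361 and 0.344 in SUM159 at 3h. The shared spread therefore favours calls in SUM159, so 190 and 2935 calls are not like for like.

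At 24h in SUM159R, calprotectin genes were among the largest changes. S100A8 and S100A9, which encode the subunits of calprotectin, rose from 6.98 ± 1.49 to 30.0 ± 3.19 FPKM (1.97 ± 0.26, adjusted p = 0.00044) and from 24.1 ± 2.93 to 84.4 ± 8.56 FPKM (1.77 ± 0.18, adjusted p = 8.5e-05). The secreted WNT antagonist gene DKK1 fell from 18.3 ± 0.539 to 6.14 ± 0.0139 FPKM (-1.44 ± 0.10, adjusted p = 9.5e-06), and KYNU (-1.62), HGF (-1.46) and the ectonucleotidase gene NT5E (-1.43) fell too. BRD2 rose by 0.54 ± 0.09 (adjusted p = 0.0023), while HEXIM1 (0.56, adjusted p = 0.079), CDKN1A (0.28, adjusted p = 0.07), IL6 (-0.21, adjusted p = 0.35) and BCL2L1 (0.03, adjusted p = 0.89) did not pass. MYC was at 101 ± 12.0 FPKM in DMSO and 169 ± 31.1 in JQ1 (0.73 ± 0.21, adjusted p = 0.044), a call that ended without any 1 of the 4 libraries (0.54 to 0.92).

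G2/M genes fell in 24 of 26 in SUM159R at 24h (25 adjusted over the list alone, camera adjusted p = 5.64e-22, adjusted p = 0.0197 with an estimated correlation), with KIF20A at -1.07, HMMR at -1.04 and the cyclin gene CCNB1 at -0.99. In DMSO alone the list rose by 24h in 25 of 26 (median 1.26 against 3h, adjusted p = 0.0641 with an estimated correlation). Inflammatory cytokines and NF-kB genes fell in 7 of 21 (12 adjusted over the list alone, camera adjusted p = 1.19e-05, adjusted p = 0.00762 with an estimated correlation). Among those called were IL8 (-1.22) and CXCL1 (-0.96). Genes of CDK inhibitors and p53 targets rose in 5 of 21 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.0197 with an estimated correlation). ABC drug transporters rose in 4 of 11 (6 adjusted over the list alone, camera adjusted p = 0.00329, adjusted p = 0.0391 with an estimated correlation). BET inhibitor induced genes rose in 4 of 14 (8 adjusted over the list alone, camera adjusted p = 0.000393, adjusted p = 0.0826 with an estimated correlation), with HIST1H2BD at 1.31. Further lists passed at the preset correlation only. MAPK feedback genes fell in 3 of 17 and rose in 1 (3 and 1 adjusted over the list alone, adjusted p = 0.075 with an estimated correlation). Basal markers fell in 7 of 17 and rose in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.075 with an estimated correlation). WNT targets fell in 2 of 11 (5 adjusted over the list alone, adjusted p = 0.075 with an estimated correlation). Mesenchymal and matrix genes fell in 6 of 27 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Cytosolic ribosomal proteins rose in 0 of 28 (0 adjusted over the list alone, adjusted p = 0.387 with an estimated correlation). In all, 1664 genes were called, 730 higher and 934 lower, and 63 changed at least 2-fold. The count was 2 with the spread of the 4 libraries compared and 3495 after the GC trend was removed.

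Whether the resistant line responds differently was tested as the response of SUM159R minus that of SUM159. At 3h CDKN1A stood at 70.3 ± 0.165 FPKM in DMSO and 83.3 ± 1.81 in JQ1 in SUM159R, and rose from 40.8 to 175 FPKM in SUM159, a difference of -1.83 ± 0.13 (adjusted p = 1.5e-05). The matrix-associated gene CTGF rose from 24.7 to 114 FPKM in SUM159 and stood at 24.5 and 27.2 FPKM in SUM159R (-2.01 ± 0.12, adjusted p = 3.3e-06), and EGR1 differed by -2.55 ± 0.24 (adjusted p = 0.0001). HEXIM1 (-1.37), SERPINI1 (-1.49) and BRD2 (-1.14) also had smaller responses in SUM159R, and those of IL6 (1.85), IL8 (1.37) and BCL2L1 (0.57) differed upward. In DMSO SUM159R held 0.767 FPKM of IL6 and 5.97 of IL8, against 10.9 and 50.8 in SUM159. The fall of DIO2 differed by 2.62 ± 0.20, but SUM159R held 1.06 ± 0.16 FPKM of DIO2 in DMSO against 55.7 ± 9.34 in SUM159. At 24h SERPINB3 (5.50), SERPINA3 (3.53) and NUPR1 (3.88) differed in the same way, with 0.0272, 1.45 and 0.606 FPKM in SUM159R in DMSO. DKK1 rose in SUM159 and fell in SUM159R at 24h, a difference of -3.13 ± 0.14 (adjusted p = 1.6e-07), and TP53I3 (-1.96), HEXIM1 (-1.30), CDKN1A (-1.20) and BRD2 (-0.54) had smaller responses in SUM159R. MYC differed by 0.97 ± 0.30 at 24h (adjusted p = 0.046) and by -0.05 at 3h (adjusted p = 0.97).

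By list at 3h, the responses of SUM159R were compared with those of SUM159. Genes induced by BET inhibitors were lower in 6 of 14 (10 adjusted over the list alone, adjusted p = 0.0299 with an estimated correlation). CDK inhibitors and p53 targets were lower in 7 of 21 and higher in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.01 with an estimated correlation). The others passed at the preset correlation only. Immediate early genes were lower in 7 of 17 (10 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). NF-kB and inflammatory cytokine genes were higher in 6 of 21 and lower in 2 (8 and 3 adjusted over the list alone, adjusted p = 0.0523 with an estimated correlation). MAPK feedback genes were lower in 5 of 17 and higher in 2 (5 and 2 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis genes were lower in 3 of 23 (3 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). MYC-linked ribosome biogenesis genes were higher in 2 of 26 (4 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). Cytosolic ribosomal proteins were lower in 0 of 28 (0 adjusted over the list alone, adjusted p = 0.459 with an estimated correlation), and their median turned from -0.20 to 0.04 after quantile normalization. Of 13153 genes, 719 differed, 414 upward and 305 downward, 115 by at least 2-fold. The count was 164 with the spread of the 8 libraries compared, unequal between the lines, and 2060 after the GC trend was removed.

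At 24h, these lists had responses that were lower or higher in SUM159R than in SUM159. BET inhibitor induced genes were lower in 11 of 14 (12 adjusted over the list alone, adjusted p = 0.0184 with an estimated correlation). MAPK feedback genes were lower in 6 of 17 (10 adjusted over the list alone, adjusted p = 0.0157 with an estimated correlation). G1/S genes were higher in 12 of 27 and lower in 1 (14 and 3 adjusted over the list alone, adjusted p = 0.0159 with an estimated correlation). Interferon-stimulated genes were higher in 10 of 24 (11 adjusted over the list alone, adjusted p = 0.0235 with an estimated correlation). Cholesterol synthesis genes were higher in 5 of 23 and lower in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0235 with an estimated correlation). Genes of ATF4 and the unfolded protein response were higher in 10 of 19 and lower in 2 (11 and 3 adjusted over the list alone, adjusted p = 0.0174 with an estimated correlation). Passing at the preset correlation only were a further 6 lists. MYC-linked ribosome biogenesis genes were higher in 9 of 26 (10 adjusted over the list alone, adjusted p = 0.0765 with an estimated correlation). Cytosolic ribosomal proteins were higher in 13 of 28 (17 adjusted over the list alone, adjusted p = 0.222 with an estimated correlation). G2/M genes were higher in 4 of 26 (4 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). WNT targets were lower in 3 of 11 and higher in 1 (3 and 1 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation). Hypoxia and glycolysis genes were lower in 6 of 20 and higher in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.222 with an estimated correlation). Genes of autophagy and the lysosome were lower in 5 of 23 and higher in 2 (6 and 3 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation). In all, 2226 genes differed, 1371 upward and 855 downward, 393 by at least 2-fold. Upward calls were 61.6% of these, 51.7% after quantile normalization and 53% after the GC trend was removed. With the spread of the 8 libraries compared the count was 1191, and after the GC trend was removed 3970.

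Across genes, the 24h responses of SUM159 and SUM159R had a Pearson r of 0.284 and a Spearman rho of 0.47. Of 1252 genes called in both lines, 91.3% changed in the same direction, and the change was smaller in SUM159R for 93.4% of the genes called in SUM159. The slope of the SUM159R response on that of SUM159 was 0.21 through the genes called in SUM159, and the slope of SUM159 on SUM159R through the genes called in SUM159R was 0.773. Selection on 1 line shrinks each slope, so neither alone measures the difference in size. The r was 0.174 without SUM159R JQ1 24h replicate 2, 0.475 with short RNA removed and 0.477 with the GC trend removed. At 3h, r was 0.1, rho 0.446 and the slope 0.205, and 146 genes were called in both lines, 96.6% in the same direction.

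**Figure D2:**
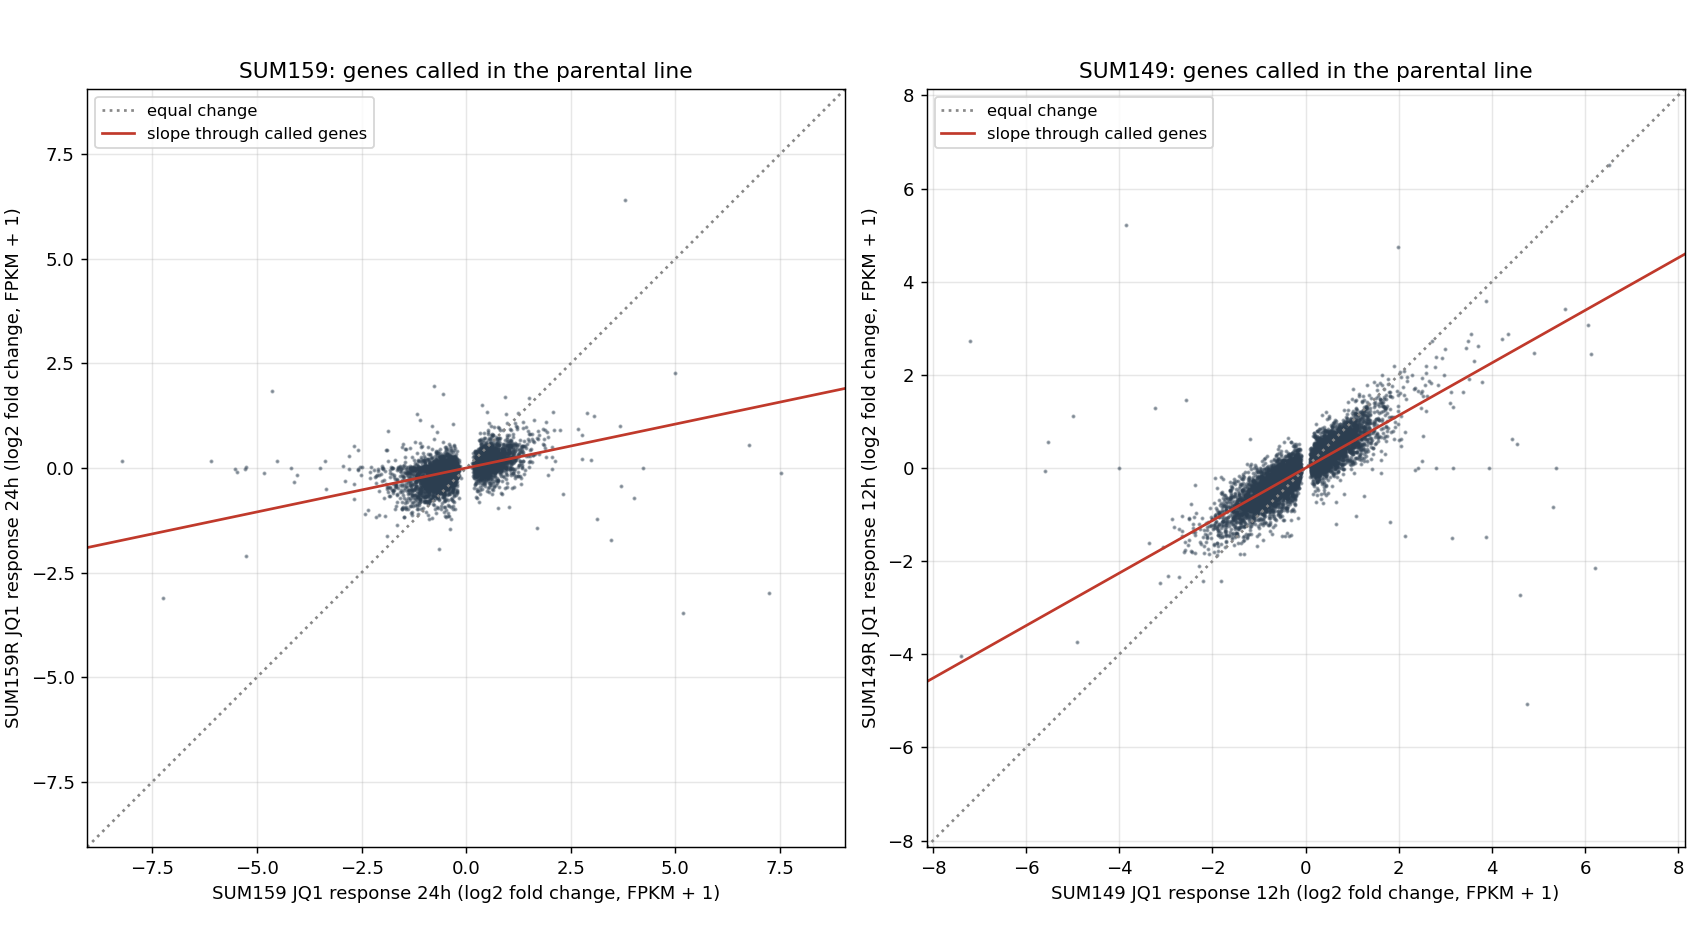
Log2 fold change with JQ1 in the resistant line (vertical axis) against the parental line (horizontal axis), SUM159 at 24h on the left and SUM149 at 12h on the right, for genes called in the parental line; the dotted line marks an equal change and the red line the slope through these genes.

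Resistant and parental cells were compared in DMSO to ask how they differ without added drug. In SUM159R the fibrillar collagen gene COL3A1 was at 0.0516 ± 0.032 FPKM at 3h and 0.461 ± 0.0801 at 24h, against 58.1 ± 1.0 and 118 ± 7.64 in SUM159 (-6.08 ± 0.06, adjusted p = 1.1e-14). The hypoxia marker CA9 (-5.23), the cytokine gene IL32 (-4.82), SERPINB3 (-4.94) and DIO2 (-5.02) were lower as well. IGFBP2, an insulin-like growth factor binding protein gene, was at 41.5 ± 0.857 and 38.0 ± 9.22 FPKM against 0.451 ± 0.206 and 0.621 ± 0.0613 (4.72 ± 0.16, adjusted p = 1.4e-10), and the sugar phosphate carrier gene SLC37A2 (3.90), the plasminogen activator gene PLAT (2.62) and CD24 (2.85) were higher. BCL2L1 was at 136 ± 2.58 FPKM in SUM159R at 3h against 44.9 ± 4.57 in SUM159 (1.38 ± 0.06 over both times, adjusted p = 8.3e-10). FOSL1 (1.59), CCND1 (1.27), CDKN1A (1.05), SERPINI1 (1.00), HEXIM1 (0.95), BRD2 (0.68) and BRD3 (0.54) were higher, while MYC (-0.10, adjusted p = 0.57) did not pass.

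Interferon-stimulated genes were lower in SUM159R in 21 of 24 and higher in 3 (21 and 3 adjusted over the list alone, camera adjusted p = 1.87e-08, adjusted p = 0.0165 with an estimated correlation), with OASL at -3.34 and IFI44 at -2.85. G1/S genes were higher in 19 of 27 and lower in 3 (19 and 3 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.0165 with an estimated correlation), with CCNE2 at 0.98. At 3h alone the list did not pass (adjusted p = 0.13 with an estimated correlation), and at 24h it did (20 higher and 2 lower, adjusted p = 0.00583 with an estimated correlation). ATF4 and unfolded protein response genes were lower in 15 of 19 (15 adjusted over the list alone, camera adjusted p = 0.000907, adjusted p = 0.0165 with an estimated correlation), with SLC7A11 at -1.73. Of these genes 10 were lower at 3h (adjusted p = 0.0801 with an estimated correlation) and 13 at 24h (adjusted p = 0.0198 with an estimated correlation). For NF-kB and inflammatory cytokines, 16 of 21 were lower and 4 higher (16 and 4 adjusted over the list alone, camera adjusted p = 0.00753, adjusted p = 0.0403 with an estimated correlation), with ICAM1 at -2.48, IL6 at -1.25 and CCL20 at 1.49. Values of this comparison are means of both times, and the contrasts at each time were chosen after seeing the data. Here 17 of 21 were lower at 3h (adjusted p = 0.00472 with an estimated correlation), while at 24h 8 were higher and 6 lower and the list did not pass (adjusted p = 0.456 with an estimated correlation). Genes induced by BET inhibitors were higher in 9 of 14 (9 adjusted over the list alone, camera adjusted p = 0.00734, adjusted p = 0.197 with an estimated correlation). At 3h 10 were higher, with a median of 1.28 (adjusted p = 0.0745 with an estimated correlation), and at 24h 4 were higher and 1 lower, with a median of -0.05. Mesenchymal and matrix genes were lower in 15 of 27 and higher in 6 (15 and 6 adjusted over the list alone, camera adjusted p = 0.00989, adjusted p = 0.224 with an estimated correlation), with COL1A1 at -4.22, and hypoxia and glycolysis in 13 of 20 with 4 higher (13 and 5 adjusted over the list alone, camera adjusted p = 0.00734, adjusted p = 0.166 with an estimated correlation). CK2 and PP2A subunits, of a protein kinase and a protein phosphatase, had 12 of 19 higher and 4 lower (12 and 4 adjusted over the list alone) and did not pass (camera adjusted p = 0.181). In all, 8040 genes were called, 4195 higher and 3845 lower, 1236 by at least 2-fold, and 5237 of the genes with a mean FPKM of at least 5 were called. The share of higher calls was 52.2%, and 46.4% after median ratio rescaling.

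In SUM149, the same drug was tested at 12h in a further triple negative line, and histone genes were among the largest rises. HIST1H2BG rose from 0.697 ± 0.106 to 49.5 ± 0.25 FPKM (4.90 ± 0.14, adjusted p = 3.1e-06). SERPINI1 rose from 3.48 ± 0.239 to 30.3 ± 0.648 FPKM (2.81 ± 0.06, adjusted p = 2.5e-06), HEXIM1 from 26.2 ± 0.693 to 110 ± 0.742 FPKM (2.03 ± 0.04, adjusted p = 2e-06) and CDKN1A from 19.3 ± 0.796 to 103 ± 1.29 FPKM (2.36 ± 0.06, adjusted p = 2.5e-06). MYC fell from 103 ± 2.89 to 45.7 ± 1.79 FPKM (-1.15 ± 0.04, adjusted p = 4.6e-06), and the cyclin D1 gene CCND1 fell from 45.8 ± 1.55 to 15.9 ± 0.759 FPKM (-1.47 ± 0.04, adjusted p = 3.3e-06). ZNF532, a zinc finger gene, fell from 14.2 ± 0.173 to 0.760 ± 0.00769 FPKM (-3.12 ± 0.05, adjusted p = 2e-06). IL6 (-0.07, adjusted p = 0.48, at 0.0968 and 0.155 FPKM) did not pass.

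In SUM149 camera passed 8 lists at the preset correlation and none with an estimated correlation. BET inhibitor induced genes rose in 14 of 14 (14 adjusted over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.135 with an estimated correlation). G1/S genes fell in 26 of 27 (26 adjusted over the list alone, camera adjusted p = 1.16e-08, adjusted p = 0.0578 with an estimated correlation), with E2F2 at -2.41 and CCNE2 at -1.81. Immediate early and AP-1 genes rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 3.13e-07, adjusted p = 0.163 with an estimated correlation). MYC-linked ribosome biogenesis fell in 21 of 26 and rose in 1 (21 and 1 adjusted over the list alone, camera adjusted p = 0.000174, adjusted p = 0.298 with an estimated correlation). Genes of CDK inhibitors and p53 targets rose in 13 of 18 and fell in 4 (13 and 4 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation). Hypoxia and glycolysis genes rose in 15 of 20 and fell in 3 (16 and 3 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation). Autophagy and lysosome genes rose in 15 of 23 and fell in 3 (15 and 3 adjusted over the list alone, adjusted p = 0.391 with an estimated correlation). Genes of ATF4 and the unfolded protein response rose in 11 of 18 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation). In all, 9501 of 13058 genes were called, 4204 higher and 5297 lower, and 1509 changed at least 2-fold. Higher calls were 44.2% of these, 50.2% after quantile normalization, 49.7% after median ratio rescaling and 50.9% after the GC trend was removed.

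SUM149R was exposed in the same way, and the histone and BET marker genes rose there too. HIST1H3H rose from 2.22 ± 0.558 to 37.1 ± 0.455 FPKM (3.58 ± 0.13, adjusted p = 2e-05), SERPINI1 rose by 2.39, CDKN1A by 1.72, HEXIM1 by 1.61 and BRD2 by 0.96 on the log2 scale. MYC fell from 155 ± 1.7 to 88.3 ± 0.838 FPKM (-0.81 ± 0.04, adjusted p = 3.6e-05), and CCND1 fell by 0.73 on the log2 scale. AMIGO2 fell from 75.5 ± 1.22 to 14 ± 0.163 FPKM (-2.35 ± 0.04, adjusted p = 5.5e-06), and NUPR1 (-2.43) and the matrix gene THBS1 (-2.10) fell. EGFR (-0.01, adjusted p = 0.93) did not pass.

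Camera passed 9 lists in SUM149R, none with an estimated correlation. Genes induced by BET inhibitors rose in 14 of 14 (14 adjusted over the list alone, camera adjusted p = 2.79e-08, adjusted p = 0.156 with an estimated correlation). G2/M genes rose in 20 of 26 and fell in 3 (21 and 3 adjusted over the list alone, camera adjusted p = 0.000959, adjusted p = 0.156 with an estimated correlation), with the checkpoint kinase gene BUB1 at 0.73. G1/S genes fell in 19 of 27 and rose in 3 (19 and 3 adjusted over the list alone, camera adjusted p = 0.00342, adjusted p = 0.156 with an estimated correlation). MYC-linked ribosome biogenesis fell in 17 of 26 and rose in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 0.00214, adjusted p = 0.333 with an estimated correlation). NF-kB and inflammatory cytokines fell in 13 of 18 and rose in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.00563, adjusted p = 0.459 with an estimated correlation), with LIF at -2.42 and IL8 at -1.84. CDK inhibitors and p53 targets rose in 13 of 18 and fell in 4 (13 and 4 adjusted over the list alone, adjusted p = 0.333 with an estimated correlation). Immediate early genes rose in 10 of 18 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.333 with an estimated correlation). Genes of autophagy and the lysosome rose in 11 of 23 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.541 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 23 and rose in 4 (15 and 4 adjusted over the list alone, adjusted p = 0.484 with an estimated correlation). In all, 8226 genes were called, 3981 higher and 4245 lower, and 579 changed at least 2-fold.

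Tested against each other, the responses of SUM149R and SUM149 differed for cell cycle genes. The cyclin gene CCNE2 fell in SUM149 from 24.0 ± 0.83 to 6.10 ± 0.244 FPKM and stood at 12.3 ± 0.892 and 10.6 ± 0.423 FPKM in SUM149R, a difference of 1.62 ± 0.09 (adjusted p = 0.00054). The methyltransferase gene NNMT fell from 70.8 to 12.9 FPKM in SUM149 and stood at 132 and 102 FPKM in SUM149R (2.00 ± 0.11, adjusted p = 0.00055). HIST1H2BG (-2.42), the stress response gene OSGIN1 (-1.71), the chaperone gene CLU (-1.75) and the keratin gene KRT15 (-1.61) differed the other way. CCND1 (0.73), BRD3 (0.50) and MYC (0.35) had more positive responses in SUM149R, and CDKN1A (-0.64), IL6 (-0.63), BRD2 (-0.51), HEXIM1 (-0.42) and SERPINI1 (-0.42) less positive ones.

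G1/S genes responded more positively in SUM149R in 27 of 27 (27 adjusted over the list alone, camera adjusted p = 4.44e-15, adjusted p = 0.02 with an estimated correlation) and G2/M genes in 21 of 26 (23 adjusted over the list alone, camera adjusted p = 9.41e-08, adjusted p = 0.0485 with an estimated correlation). The other lists passed at the preset correlation only. Immediate early and AP-1 genes were lower in 15 of 18 (16 adjusted over the list alone, adjusted p = 0.0567 with an estimated correlation). Basal markers were lower in 8 of 21 (10 adjusted over the list alone, adjusted p = 0.0567 with an estimated correlation). BET inhibitor induced genes were lower in 8 of 14 (8 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). Hypoxia and glycolysis genes were lower in 11 of 20 (14 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 23 and higher in 0 (10 and 1 adjusted over the list alone, adjusted p = 0.158 with an estimated correlation). ATF4 and unfolded protein response genes were lower in 11 of 18 and higher in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). Genes of CDK inhibitors and p53 targets were lower in 8 of 18 and higher in 2 (8 and 4 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation). Autophagy and lysosome genes were lower in 9 of 23 and higher in 0 (9 and 1 adjusted over the list alone, adjusted p = 0.248 with an estimated correlation). NF-kB and inflammatory cytokine genes were lower in 7 of 18 and higher in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation). Luminal markers were lower in 5 of 18 and higher in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.436 with an estimated correlation). Mesenchymal and matrix genes were higher in 10 of 20 (10 adjusted over the list alone, adjusted p = 0.114 with an estimated correlation). MYC-linked ribosome biogenesis genes were higher in 11 of 26 and lower in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation). Cytosolic ribosomal proteins were lower in 0 of 28 (0 adjusted over the list alone, adjusted p = 0.714 with an estimated correlation), with a median of -0.07 that was 0.01 after quantile normalization. In all, 4062 genes differed, 2695 upward and 1367 downward, 179 by at least 2-fold. The share of upward calls was 66.3%, 54.3% after quantile normalization, 54.4% after median ratio rescaling and 51.9% after the GC trend was removed. The count was 2607 without SUM149R JQ1 12h replicate 1 and 2492 without SUM149R JQ1 12h replicate 2.

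Without added drug, SUM149R was compared with SUM149, and the keratin genes KRT16, KRT5 and KRT14 were among the largest rises. KRT16 was at 119 ± 10.3 against 9.34 ± 1.16 FPKM (3.54 ± 0.09, adjusted p = 8.6e-06), KRT5 at 526 ± 5.9 against 78.9 ± 2.01 FPKM (2.72 ± 0.04, adjusted p = 3.1e-06) and KRT14 at 15.1 ± 0.963 against 1.32 ± 0.0228 FPKM (2.79 ± 0.06, adjusted p = 5.4e-06). The carboxylesterase gene CES1 rose from 0.0146 ± 0.00377 to 15.6 ± 0.402 FPKM (4.04 ± 0.04, adjusted p = 7.7e-07), and IL6 from 0.155 ± 0.0951 to 3.40 ± 0.411 FPKM (1.93 ± 0.09, adjusted p = 3.2e-05). The glutamine synthetase gene GLUL fell from 15.3 ± 0.066 to 0.999 ± 0.206 FPKM (-3.03 ± 0.07, adjusted p = 6.3e-06), and fibronectin, FN1, fell by 2.15 on the log2 scale. BCL2L1 (0.67), CCND1 (0.67), MYC (0.59), FOSL1 (0.52) and SERPINI1 (0.29) were higher, BRD2 (-0.55) and HEXIM1 (-0.23) lower, and CDKN1A (0.02, adjusted p = 0.76) and EGFR (-0.30, adjusted p = 0.084) did not pass.

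No list of the SUM149R and SUM149 comparison in DMSO passed with an estimated correlation. Basal markers were higher in 16 of 21 and lower in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 0.000353, adjusted p = 0.16 with an estimated correlation), and mesenchymal and matrix genes lower in 15 of 20 and higher in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.000845, adjusted p = 0.16 with an estimated correlation), with SNAI1 at -2.19. Hypoxia and glycolysis was lower in 14 of 20 and higher in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.000845, adjusted p = 0.404 with an estimated correlation), with the glucose transporter gene SLC2A1 at -1.49. NF-kB and inflammatory cytokines were higher in 14 of 18 and lower in 3 (14 and 3 adjusted over the list alone, camera adjusted p = 0.00092, adjusted p = 0.404 with an estimated correlation), with IL8 at 2.18 and CXCL1 at 1.96. MYC-linked ribosome biogenesis genes were higher in 17 of 26 and lower in 3 (18 and 3 adjusted over the list alone, adjusted p = 0.404 with an estimated correlation). Genes induced by BET inhibitors were higher in 9 of 14 and lower in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.404 with an estimated correlation). BCL2 family genes were higher in 9 of 17 and lower in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.404 with an estimated correlation). Immediate early genes were higher in 12 of 18 and lower in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.404 with an estimated correlation). MAPK feedback genes were higher in 11 of 15 and lower in 3 (11 and 3 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). YAP/TEAD targets were higher in 13 of 19 and lower in 4 (13 and 4 adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). Genes of ATF4 and the unfolded protein response were higher in 9 of 18 and lower in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). Genes of autophagy and the lysosome were higher in 14 of 23 and lower in 3 (14 and 3 adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 23 and higher in 4 (14 and 4 adjusted over the list alone, adjusted p = 0.425 with an estimated correlation). In all, 8204 genes were called, 4278 higher and 3926 lower, 522 by at least 2-fold.

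**Figure D3:**
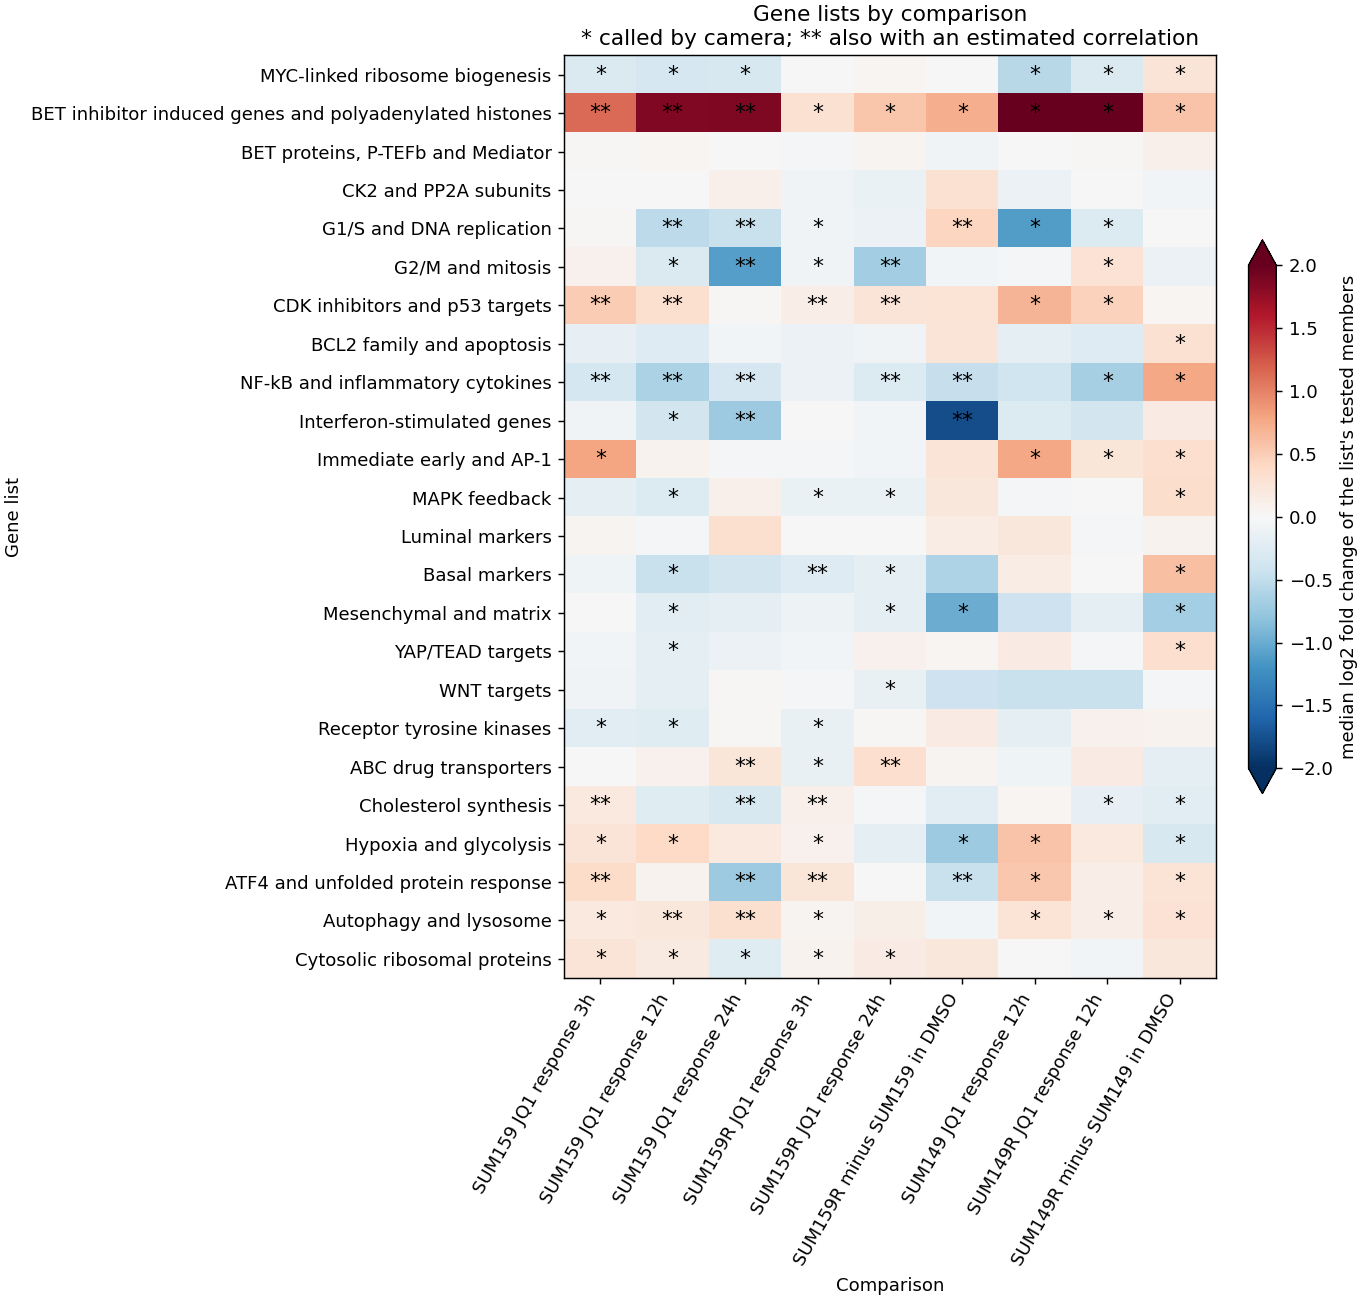
Median log2 fold change of the tested members of 24 gene lists (vertical axis) in 9 comparisons (horizontal axis), with the colour limited at 2 in each direction; a star marks a list that passed camera at the preset correlation and a pair of stars one that also passed with an estimated correlation.

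The lines were then compared by their changes across genes. The 12h responses of SUM159 and SUM149 had a Pearson r of 0.517 and a Spearman rho of 0.729 over 11958 genes, and of 3211 genes called in both, 3108 (96.8%) changed in the same direction. Both were higher for 1408 genes, where chance gave 552, and both lower for 1700, where chance gave 767. SUM149 and SUM149R had r of 0.604 and rho of 0.818, 7189 genes called in both, 96.7% in the same direction, and a slope of 0.564 through the genes called in SUM149 (0.992 in reverse), with a smaller change in SUM149R for 81.1% of them. Differences between resistant and parental cells in DMSO had little relation between the lines (r 0.0656, rho 0.121), and of 4718 genes called in both, 60.4% had the same direction. The SUM159R value is a mean of 3h and 24h and SUM149R is at 12h, so unlike times could lower r. Cytosolic ribosomal proteins of SUM159R were higher in 27 of 28 at 3h and lower in 18 at 24h. The SUM159R minus SUM159 difference in DMSO and the 12h JQ1 response of SUM159 had r of 0.35 and rho of 0.417, and of 3172 genes called in both, 81.5% had the same direction. Short RNA removal raised these r values to 0.77, 0.875, 0.118 and 0.455 in that order. Lists of BET proteins with P-TEFb and Mediator, and of CK2 and PP2A subunits, did not pass camera in any of the 13 comparisons. In DMSO contrasts of SUM159R with SUM159 chosen later, both passed for the time courses and the latter at 24h, at the preset correlation only.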

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

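The differences of responses were planned, and the removal of the GC trend and the comparison of slopes at 3h and 24h were chosen only after the result was seen. Responses to JQ1 differed between SUM159R and SUM159 for 719 genes at 3h and 2226 at 24h, between 24h and 3h in SUM159 for 3681 genes, and between SUM149R and SUM149 for 4062 genes.

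At 3h, the SUM159R response was below that of SUM159 for CDKN1A (-1.83), SERTAD1 (-2.00), CTGF (-2.01), ZFP36 (-2.15) and EGR1 (-2.55), and for HEXIM1 (-1.37), SERPINI1 (-1.49) and BRD2 (-1.14) among the fixed genes. It was above for DIO2 (2.62), IL7R (1.82), IL8 (1.37), AMIGO2 (1.33) and CMKLR1 (1.29), and for IL6 (1.85) and BCL2L1 (0.57). DIO2, IL7R, CMKLR1, IL6 and IL8 were at 1.06, 0.101, 1.26, 0.767 and 5.97 FPKM in SUM159R in DMSO, below SUM159, and the calls of IL7R and CMKLR1 ended with a smaller pseudocount. The SERTAD1 and ZFP36 calls ended without any 1 of the 4 SUM159R libraries at 3h or without the first replicate of SUM159 DMSO or SUM159 JQ1.

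At 24h, SUM159R was below SUM159 in response for CSPG4 (-1.95), TP53I3 (-1.96), LFNG (-2.07), DKK1 (-3.13) and RNU4ATAC (-4.74), and for HEXIM1 (-1.30), CDKN1A (-1.20) and BRD2 (-0.54). It was above for SERPINB3 (5.50), SERPINB4 (5.29), NUPR1 (3.88), SERPINA3 (3.53) and NFE2 (3.20), of which SERPINB4 was listed at 0 in SUM159R in DMSO and the others had 0.0272, 0.606, 1.45 and 0.645 FPKM, and for IL6 (1.29) and MYC (0.97). The RNU4ATAC call ended without replicate 2 of SUM159R DMSO (-4.11) or JQ1 (-3.94). It also ended without replicate 1 of SUM159 DMSO (-3.02) or either replicate of SUM159 JQ1 (-4.45, -5.03).

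Between 24h and 3h in SUM159, the response was lower at 24h for PMAIP1 (-2.79), SERPINA3 (-3.53), NUPR1 (-3.69), SERPINB4 (-5.12), SERPINB3 (-5.42), CDKN1A (-0.59) and BRD2 (-0.37). It was higher for DKK1 (3.20), AMIGO2 (2.44), C10orf54 (2.19), CYP1A1 (1.96), PCDH7 (1.94), EGFR (1.23), BCL2L1 (1.13) and CCND1 (0.74). In DMSO at 3h and 24h, DKK1 stood at 162 and 15.3 FPKM, AMIGO2 at 27.1 and 3.57 and PCDH7 at 33.8 and 6.76, while with JQ1 they stood at 56.4 and 51.6, 6.42 and 5.54, and 14.5 and 12.3.

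At 12h, SUM149R was below SUM149 in response for KRT15 (-1.61), OSGIN1 (-1.71), CLU (-1.75), C1orf116 (-1.84), HIST1H2BG (-2.42), CDKN1A (-0.64), IL6 (-0.63), BRD2 (-0.51), HEXIM1 (-0.42) and SERPINI1 (-0.42). It was above for NNMT (2.00), SCARNA16 (1.83), C11orf86 (1.79), TMEM200B (1.69), CCNE2 (1.62), CCND1 (0.73), BRD3 (0.50) and MYC (0.35). The SCARNA16 call ended without SUM149 DMSO 12h replicate 2 (1.66) or SUM149 JQ1 12h replicate 2 (1.64).

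The smaller response of SUM159R at 24h could be a technical effect of GC content or a lasting effect of earlier JQ1. If GC content were the cause, the slope should pass 0.5 with the GC trend removed. It moved from 0.21 to 0.264 (0.253 to 0.264 without any 1 library). Selection on SUM159 calls and genes near 0 FPKM in SUM159R shrink this slope, so the test cannot tell. If JQ1 left from culture had acted in the DMSO cells and faded, the SUM159R difference in DMSO should follow the 12h JQ1 response of SUM159 with under 0.5 of the slope at 24h as at 3h, and with over 0.8 of it if not, and the ratio was 0.561 (0.539 to 0.581 without any 1 library). Different growth at 24h could give the same ratio, and values point both ways, as the BET inhibitor induced list had a median difference of 1.28 at 3h and -0.05 at 24h (time courses adjusted p = 0.0904 with an estimated correlation) while HEXIM1 was further above SUM159 at 24h (1.15) than at 3h (0.74), so this stays open. A washout series of SUM159R sampled over several days without JQ1 would tell them apart.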

How the results depend on the processing

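The labels given here are limits of size, and the cause was not tested unless named. With a mean FPKM of at least 5 fewer genes were tested, and the counts were 1828, 2588 and 3566 in SUM159 at 3, 12 and 24h, 109 and 1093 in SUM159R at 3 and 24h, 356 and 1232 for the differences of responses at 3 and 24h, 2399 for 24h minus 3h and 5237 for SUM159R minus SUM159 in DMSO. With only the groups compared fewer libraries set the spread, and the counts were 4, 2442 and 2696 in SUM159, 8 and 2 in SUM159R, 164 and 1191 for the differences and 1272 for 24h minus 3h. Quantile normalization gave 72 in SUM159R at 3h, and in SUM159 at 3h it turned RPS9 to -0.02, RPL27 to -0.09 and RPLP0 to -0.09. With the GC trend removed, chosen after seeing the data, counts were 4954 in SUM159 at 3h, 888 and 3495 in SUM159R, and 2060 and 3970 for the differences. The residual component as covariate, also chosen after seeing the data, gave 6104, 7022 and 8312 in SUM159, 1617 and 4463 in SUM159R, 2967 and 5257 for the differences and 6940 for 24h minus 3h, and it is taken from the residuals themselves, so it lowers the spread by construction. Of 141 list calls, 48 passed with an estimated correlation, and fry gave 223. The correlation of SUM159 and SUM149 at 12h was 0.44 with the pseudocount lowered, 0.77 with short RNA removed, 0.777 with the GC trend removed and 0.697 over genes called in either. In these last 3 settings that of SUM159 and SUM159R at 24h was 0.475, 0.477 and 0.436. That of SUM149 and SUM149R was 0.875, 0.877 and 0.751 (0.528 with the pseudocount lowered, 0.53 with a mean FPKM of at least 5). That of the resistant minus parental differences was 0.118, 0.123 and 0.116 (0.0128 with a mean FPKM of at least 5). For SUM159R minus SUM159 against the 12h response it was 0.455, 0.455 and 0.454. The GC setting gave nearly the same r as short RNA removal, so these do not show separate effects. Leaving out 1 library gave 43 to 63 in SUM159R at 3h, 835 to 910 in SUM159R at 24h, 437 to 707 for the difference at 3h and 2492 to 3647 for the difference of SUM149R and SUM149, and fewer degrees of freedom are part of it by construction. Of 510 named calls, 352 were kept under every setting, 158 ended under at least 1 and 3 reversed.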

Other observations

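All contrasts of time in DMSO, the contrasts of SUM159R with SUM159 at each time, and the tests on GC content and transcript length were chosen only after the result was seen. In DMSO alone, 7460 genes changed between 3h and 24h in SUM159 and 6846 in SUM159R, and the time courses differed for 5749. The lines differed by a similar number of genes at 3h (7235) and at 24h (7189). In SUM159 the feedback genes of the MAPK pathway fell in 15 of 17 (adjusted p = 0.000958 with an estimated correlation), with DUSP6 at -3.02 and SPRY4 at -2.37. They did not fall alone, as G1/S genes fell in 26 of 27 (adjusted p = 0.000223 with an estimated correlation) and MYC-linked ribosome biogenesis genes in 25 of 26 (adjusted p = 0.00621 with an estimated correlation). In SUM159R G1/S genes fell in 19 of 27 (adjusted p = 0.00281 with an estimated correlation) and MYC-linked ribosome biogenesis genes in 21 of 26 with 1 higher (adjusted p = 0.0194 with an estimated correlation). MAPK feedback genes did not pass there, with 9 higher and 4 lower of 17 (adjusted p = 0.168 with an estimated correlation), nor did immediate early genes, with 3 higher and 4 lower of 17 (adjusted p = 0.794 with an estimated correlation), although DUSP6 rose by 1.25 and EGR1 by 2.47. Among NF-kB and inflammatory cytokine genes, SUM159R had 14 of 21 higher at 24h and 1 lower (adjusted p = 0.00556 with an estimated correlation), with IL6 at 2.55 and CXCL2 at 2.31.

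The time course of SUM159R minus that of SUM159 was upward for 16 of 17 MAPK feedback genes and downward for 1 (adjusted p = 0.000694 with an estimated correlation), with DUSP6 at 4.27 and SPRY4 at 2.21. For NF-kB and inflammatory cytokines it was upward in 16 of 21 (adjusted p = 0.000824 with an estimated correlation), with IL8 at 4.51 and IL6 at 3.01. Also upward were G1/S genes (15 of 27 and 3 downward, adjusted p = 0.0198 with an estimated correlation), cholesterol synthesis (12 of 23 and 1 downward, adjusted p = 0.0198 with an estimated correlation) and WNT targets (8 of 11 and 1 downward, adjusted p = 0.0256 with an estimated correlation). MAPK feedback genes were lower in SUM159R than in SUM159 at 3h in 12 of 17 with 4 higher (adjusted p = 0.0441 with an estimated correlation), and higher at 24h in 15 of 17 with 1 lower (adjusted p = 0.00583 with an estimated correlation).

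Libraries of the same SUM159 or SUM159R group stood apart along 1 axis that held 77% of the within-group variance without short RNA. If GC content of the transcripts drove it, gene weights on the axis should follow GC content, and rho was 0.792, which fits. If transcript length drove it, they should follow length, and rho was -0.278, which cannot tell. If cultures grew at different rates, mitotic genes should lie at an extreme, and the G2/M list lay at percentile 2.16 of 10000 matched lists, so growth may also have part in it. Libraries of the same RNA made again with a set input would tell a technical cause from growth.

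The difference of SUM159R and SUM159 in DMSO was compared with other splits of the 8 libraries into 4 and 4, with time as a term (1 could not be estimated). The real split called 5066 genes, and no other of the 34 called more than 243. Other splits mix the lines, which widens their spread, so chance is not tested.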
